A study of Drosophila melanogaster with 3 samples.

How the data were processed

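RNA immunoprecipitation followed by sequencing (RIP-seq) recovers a protein with an antibody and sequences the RNA that comes with it. Per the labels, the protein was Fmr1, the fly homolog of the fragile X protein FMRP, and the cells were Drosophila melanogaster S2R+ cells, a cultured line that attaches to the dish. The cells carried HA-tagged and FLAG-tagged copies of Fmr1, each tag at the C terminus and each copy behind the promoter of the metallothionein gene MtnA, and were treated with copper sulfate at 0.35 mM over 24 hours. The labels give 1 group of 3 biological replicates, chemical fragmentation and a size range above 200. They also name a possible control experiment, which was not analysed here. A level reported here is therefore a level in the immunoprecipitate and not an enrichment over the RNA of the cell. Comparisons were made between features within a library, and between the replicates of the group.

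The authors deposited, for each replicate, a normalized signal of all reads per base of dm3, with both strands together, per the descriptions that accompany the files. The replicates were not pooled. Every deposited signal value was a whole multiple of the smallest value in its library (100% of values, within 0.01 of a step), and signal times length summed to the same total in each library. The values therefore behave as coverage by reads of 50 bp, scaled to a fixed number of reads, and the step gives the depth: 6790402 reads in replicate 1, 9765133 in replicate 2 and 26655942 in replicate 3. Intervals with no reads are left out of the files. The aligner, its filters and its treatment of reads that fit several places are not given in the sources used here. Reads that fit paralogs, repeated genes or 2 overlapping genes on opposite strands can therefore not be assigned with certainty.

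Each library was divided by its own mean signal per base over 2L, 2R, 3L, 3R, 4 and X (120.352 Mb), and this scaled signal is the unit of all levels. A scaled signal of 1 over a 1000-bp tile stands for 34.2 reads in replicate 1, 55.8 in replicate 2 and 196 in replicate 3. Log2 values used a pseudocount of 0.1, so log2 ratios of weakly covered features understate the difference. Tiles with a mean scaled signal of at least 0.1 entered the agreement of the replicates. A gene counted as detected at a scaled signal of at least 0.5 in each of the 3 libraries. The share floor of a sequence with no reads was set at 3 reads. PCR copies cannot be told from independent molecules, so floors cover counting error only.

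No reference genome was given. Annotation in dm3 coordinates was taken from installed software packages, as planned. The positions of 26454 RefSeq transcript starts came from the dm3 upstream sequences in Biostrings 2.70.1. Of these, 25847 were named through their accession in a RefSeq gene table of Release 6, which was used for names only, and they gave 12500 genes with a start on the arms. FlyBase release 5 gene models (r5.49) in gffutils 0.14 cover 2L from its start to position 4448391. They hold 631 genes, 625 of them named through the locus tag, and 609 were used, 535 of them protein-coding. At 501 of 519 genes found in both sources (96.5%) a RefSeq start equalled the gene start of the release 5 models. Gene models for the other arms were not used here.

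The level of a gene across the genome was the mean scaled signal in the 250 bp downstream of its transcript start, taking its highest start. This window covers only the 5′ end of a gene and runs into the intron where exon 1 is short. In the interval of 2L the level was the mean over exonic bases that belong to no other gene. A gene list was called high or low where its median log2 level lay, in every library, in the top or bottom 2.5% of 10000 random lists of the same size. This percentile describes these libraries and is not a test across replicates. The lists held copper response genes, heat shock proteins, mRNAs described as Fmr1 targets, small RNA and mRNP proteins, cytosolic and mitochondrial ribosomal proteins, translation factors, glycolysis, the proteasome core, actin cytoskeleton genes, the dosage compensation complex, hemocyte markers, markers of neurons, muscle, fat body, germ line and epithelia, chemosensory receptors, and odorant binding and seminal fluid proteins. In the 2L interval, lists of spliceosomal and nucleolar small RNAs and of transfer RNAs were added, for 21 lists in all. The name nos was left out of 2 lists because several genes hold it as a synonym.

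For each gene of the 2L interval, log2 ratios of 3′ UTR over CDS, of 5′ UTR over CDS and of the 3′ part over the 5′ part of the exons, divided at the middle, were tested against 0 with limma 3.58.1 in R 4.3.3 and Benjamini-Hochberg adjustment at 0.05. Each part needed at least 100 bp and the mean scaled signal over both parts at least 0.5. Bases in both classes or in another gene were left out. The limma model takes no account of a shift shared by all genes of a library. In both UTR comparisons it gave every gene the same pooled standard error. Those p-values therefore do not measure the spread of a single gene between replicates. Ratios of a whole library were compared with 0 by a two-sided exact sign-flip permutation test, whose smallest p is 0.25 with 3 libraries and 0.5 with 2, so no such test could reach 0.05. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots used matplotlib 3.10.9.

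The limma step was tested on simulated ratios with the real spread of each gene. The simulated genes varied independently, without a shift shared by all genes of a library. The false calls below therefore do not carry over to real ratios that hold such a shift. For 3′ UTR over CDS (166 genes) it recovered 0% of ratios of 1 and 40% of ratios of 2 on the log2 scale, with 1 false call among 9 calls. For 5′ UTR over CDS (157 genes) it recovered 40% and 94.7%, with 0 false calls among 26. For the 3′ over the 5′ part (237 genes) it recovered 86.7% and 100%, with 2 false calls among 57. Of 200 random lists of 20 genes, 3.5% came out high in replicate 1, against 82.5% of 200 lists drawn from detected genes.

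The comparisons, lists, alternatives and the rule for named genes were chosen before the data were examined. The trend of replicate differences with exonic length and the ratio of the Fmr1 body to its start window were not among these planned comparisons. The rule names Fmr1, the Mtn genes and msl-2, the 10 genes of the 2L interval with the highest level, the 3 highest members of each list, the 5 largest and 5 smallest ratios past the threshold in each UTR comparison, and the 5 detected genes of the interval with the largest SD of log2 level. The highest runs of tiles, given by coordinates, and any other gene named were chosen after their values were seen. The alternatives covered tile size, filters, pseudocount, scaling, window, choice of start, gradients along the transcript, limma with a trend, and leaving out each replicate in turn. Text descriptions that accompany the files hold no measurement and were not used as data.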

Results

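Fmr1 was immunoprecipitated from S2R+ cells that expressed tagged Fmr1 in the presence of copper, and the RNA recovered with it was sequenced in 3 biological replicates of 1 group. Fmr1 is an RNA-binding protein that acts on the translation and transport of mRNAs, and which RNAs come down with it is the question such an experiment addresses. Depth was 6790402, 9765133 and 26655942 reads in replicates 1, 2 and 3, of which 60.6%, 68.8% and 88.4% lay on 2L, 2R, 3L, 3R, 4 and X. Reads covered 16.9%, 18.2% and 23.4% of the bases of these arms. Levels are scaled signal, in which 1 is the mean of the library over the arms of dm3, and errors are SDs over the 3 replicates. No control library was analysed here, so a high level can reflect an abundant RNA as well as a bound RNA.

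Replicates 1 and 2 were closer to each other than either was to replicate 3. Across 32318 tiles of 1000 bp, which are not independent replicates, Pearson's r of log2 scaled signal was 0.964 between replicates 1 and 2, 0.826 between 1 and 3, and 0.885 between 2 and 3. More than 2-fold differences were found in 4.28%, 37.6% and 27.9% of these tiles. Among detected genes of the annotated interval of 2L, those with the largest SD of log2 level between replicates were snRNA:LU, Taf10b, CG15387, Nnf1b and CG13692. Taf10b, which encodes a subunit of the general transcription factor TFIID, had levels of 58.5, 38.2 and 4.21 in replicates 1, 2 and 3. CG15387 had 20.8, 13.6 and 1.58, Nnf1b, which encodes a kinetochore protein, 18.1, 11.5 and 1.89, and CG13692 15.5, 10.7 and 1.82. The noncoding gene snRNA:LU had 12.3, 0.548 and 1.1. The difference between replicates followed the length of the mRNA. Over 237 mRNA genes, Spearman's rho between exonic length and the log2 difference of replicate 3 minus replicate 1 was 0.65. The median difference was -1.34 for genes of 497 to 1246 bp and 0.39 for genes of 3261 to 22888 bp. Levels of gene groups with short mRNAs are therefore given per replicate.

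**Figure D1:**
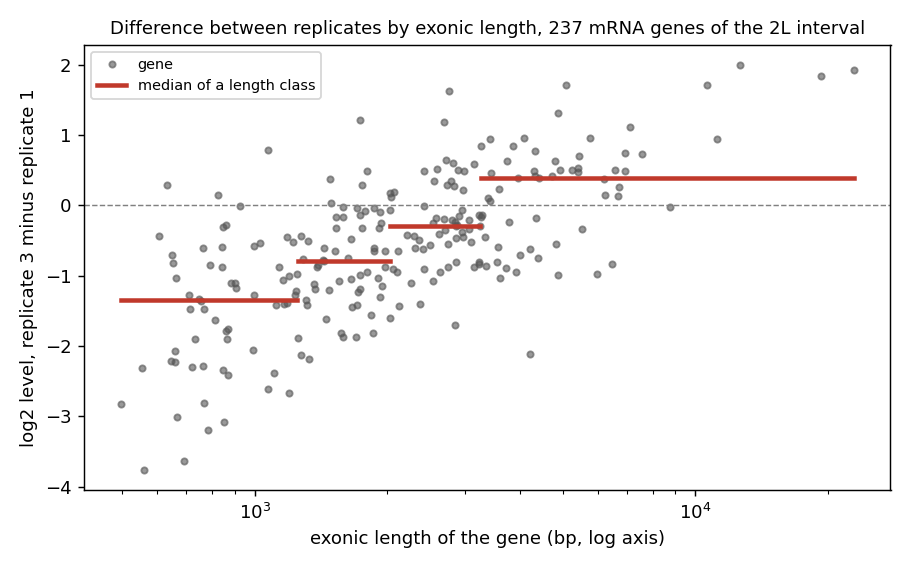
Log2 level of replicate 3 minus replicate 1 on the vertical axis against exonic length in bp on a log horizontal axis, with a point for each of 237 mRNA genes of the 2L interval. Red bars span 4 length classes at their medians, which are -1.34, -0.78, -0.30 and 0.39.

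By the mean over libraries, Fmr1 itself held the highest run of tiles on the arms, although in replicate 1 the runs at X 5725001 to 5727000 (576) and at Arc1 (545) were above it. The run at 3R 5929001 to 5932000, 2064 bp downstream of the nearest Fmr1 start, had a level of 611 ± 162 (SD, n = 3), with 453, 603 and 777 in replicates 1, 2 and 3. Within the locus the signal stood in blocks, whose limits were chosen after the values were seen. The stretches 5928901 to 5929500 and 5930001 to 5931800 had 705 ± 232 and 791 ± 194, and the stretch between them, 5929501 to 5930000, had 0.101 ± 0.0772. On the 3′ side of these blocks, 5927301 to 5928900 had 6.99 ± 0.365. This small SD joins unlike parts. In bins of 100 bp from 5927301 to 5928500, replicate 3 was always the lowest. In the bins from 5928701 and 5928801, next to the high block, it had 40.8 and 28.8, against 10.6 and 8.11 in replicate 1. Toward the 5′ end, 5934401 to 5934800 had 25.4 ± 26.2 (9.22, 11.3 and 55.6 in replicates 1, 2 and 3) and 5935501 to 5935700 had 8.17 ± 3.11. Exon models of 3R were not used here, so these blocks were not assigned to exons or introns. By the mean over libraries Fmr1 stood at place 554 of 12500 genes, and at 2167, 1235 and 151 in replicates 1, 2 and 3. The highest start window of Fmr1, from 5934945 on the minus strand, had 11.5 ± 10.8 (4.75, 5.87 and 24.0). Without replicate 1, 2 or 3 this window had a mean of 14.9, 14.4 or 5.31, and the highest start of Fmr1 had 19.0 with a window of 500 bp and 0.0828 with 100 bp.

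**Figure D2:**
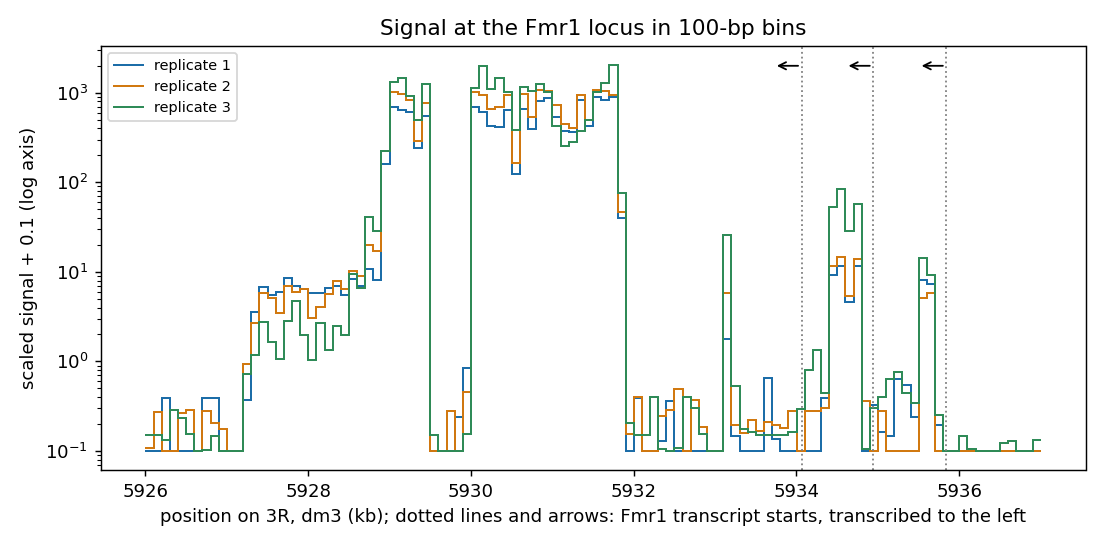
Scaled signal plus 0.1 in bins of 100 bp (log vertical axis) along the Fmr1 locus on 3R of dm3 (horizontal axis in kb), with a line for each of the 3 replicates. Dotted lines mark the transcript starts at 5934064, 5934945 and 5935843, and the blocks at 5928901 to 5929500 and 5930001 to 5931800 stand at 705 and 791 on average.

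Of 5 listed metallothionein genes, which encode small cysteine-rich proteins that bind copper and other metals, MtnA, MtnE and MtnD had high levels and MtnB and MtnC did not. MtnA, whose promoter drives the tagged copies of Fmr1, had the highest mean start window of 12500 genes, although Arc1 was above it in replicates 1 and 2, with 492 ± 181 (SD, n = 3; 699, 417 and 360 in replicates 1, 2 and 3) downstream of 3R 5610092. MtnE had 62.3 ± 41.9 (102, 65.6 and 18.9), MtnD 25.1 ± 20.1 (46.4, 22.4 and 6.45) and MtnB 3.26 ± 1.02, at places 44, 171 and 2522 by the mean. In replicates 1, 2 and 3 the places were 36, 33 and 214 for MtnE and 101, 180 and 902 for MtnD. Those of MtnB were 2438, 2291 and 2576. MtnC had 0 in replicates 1 and 2 and 0.0118 in replicate 3. Without replicate 1 the means of MtnE and MtnD were 42.2 and 14.4, and with windows of 100 bp they were 24.6 and 13.5. MtnD and MtnE start at 16360684 and 16360426 of 3R on opposite strands and point away from each other. The whole copper list, which adds copper transporters and chaperones, had a median log2 level of 1.95, 1.80 and 1.66 in replicates 1, 2 and 3, was high in every library, and had 10 of 12 members detected. The extent of the MtnA promoter in the transgenes is not given in the sources used here.

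mRNAs described as targets of Fmr1 in flies stood high as a list, which was fixed from prior knowledge and not on these libraries. Its 18 members had a median log2 level of 2.30, 1.97 and 2.90 in replicates 1, 2 and 3, and 14 were detected. The mean of the 3 medians, 2.39, became 1.72 with windows of 100 bp and 1.80 with the mean over starts. Arc1, which encodes a capsid-forming protein related to retrotransposon Gag, had 414 ± 316 (SD, n = 3; 700, 467 and 74.9) downstream of its start at 2R 10247799, which was above MtnA in replicates 1 and 2 and far below it in replicate 3. The mRNA of tral, an mRNP component, had 58.9 ± 47.4 (31.7, 31.4 and 114), and that of Pp2A-29B, the scaffold subunit of protein phosphatase 2A, 29.8 ± 18.5 (45.3, 34.8 and 9.26). The list of small RNA and mRNP proteins, which also holds tral, had medians of 2.61, 2.19 and 1.73, with 22 of 23 members detected. AGO2, the Argonaute of the siRNA pathway, had 52.0 ± 39.8 (25.3, 33.0 and 97.8) and pAbp, the poly(A)-binding protein, 38.5 ± 5.45. Both lists were high in every library, and neither shows binding, since no input RNA was compared. The random lists draw on all genes, so a list of expressed genes often comes out high for that reason alone. In replicate 1 this held for 82.5% of 200 random lists of 20 detected genes. The same limit applies to each list called high. At Arc1, tral and AGO2 replicate 3 lay farthest from the other libraries.

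By their start windows, mRNAs of the protein synthesis machinery were high in every library, with lower medians in replicate 3. These windows cover only the 5′ end of a gene, so a difference between replicates there need not hold over the whole mRNA. This limit applies to each list and start window. The 85 cytosolic ribosomal protein genes had median log2 levels of 4.11, 3.34 and 2.57 in replicates 1, 2 and 3, and 79 were detected. The mean of these medians was 3.34, against 4.99 with windows of 500 bp. RpL41 had 133 ± 60.4 (SD, n = 3), RpS28b 127 ± 33.4 and RpL21 95.7 ± 66.4. Translation factors had 3.83, 3.07 and 2.19, with 16 of 19 members detected. Among them the elongation factors eEF2, eEF1alpha1 and eEF1gamma had 96.1 ± 24.9, 63.4 ± 29.7 and 55.6 ± 15.7. The 72 mitochondrial ribosomal protein genes, most of which encode short mRNAs, had 2.12, 1.53 and -0.03, and 53 were detected. In that list mRpS33 had 34.0 ± 28.1 (60.6, 36.6 and 4.65), mRpL23 13.3 ± 11.3 (24.6, 13.5 and 1.92) and mRpS14 7.97 ± 2.97. The 14 proteasome core genes had 3.11, 2.53 and 1.37, with 13 detected. Prosbeta5 had 25.2 ± 17.9 (41.9, 27.4 and 6.22), Prosbeta1 13.9 ± 9.0 and Prosbeta6 12.3 ± 7.32. How reads that fit several places were treated is not given in the sources used here, so members with a close paralog are uncertain.

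Other housekeeping groups were high as well. Actin cytoskeleton genes had median log2 levels of 3.57, 3.05 and 2.73 in replicates 1, 2 and 3, and 23 of 23 were detected. In this group tsr, the fly cofilin, had 71.4 ± 44.8 (SD, n = 3), Act5C, a cytoplasmic actin, 53.0 ± 55.9 (114, 40.6 and 4.39), and Arp3, a subunit of the Arp2/3 complex, 27.2 ± 15.2. Over the run of tiles at Act5C the level was 270, 291 and 264 in replicates 1, 2 and 3. The fall in its start window was therefore not seen over that run. Glycolysis genes had 3.29, 2.69 and 2.52, with 13 of 14 detected. Among these Gapdh1 had 40.2 ± 10.5, Ldh 27.4 ± 23.7 (15.3, 12.2 and 54.8) and Hex-A 20.7 ± 2.66. Heat shock proteins had 2.68, 2.00 and 2.21, with 12 of 18 detected, led by the constitutive chaperones Hsc70-4 at 156 ± 31.0, Hsp83 at 82.7 ± 53.7 and Hsp60A at 12.9 ± 6.27. The copies of Hsp70 share nearly all of their sequence, and their members could not be told apart. With windows of 100 bp the mean of the heat shock medians was -0.71 and the list was no longer high. The 5 genes of the dosage compensation complex had 1.23, 0.98 and 0.42 and were not high in every library. Its members msl-1, mof and mle had 5.35 ± 1.69, 2.78 ± 0.0522 and 1.56 ± 0.887. The start window of msl-2, the member that is translated in males and repressed in females, had 1.28 ± 0.333, and its exons at 2L 3462213 to 3466111 had 3.03 ± 1.21.

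Few markers of other cell types were detected. None of these lists was called low in every library, but lists of 9 to 21 members could not be. In replicate 1 the neuronal, muscle, epithelial and fat body medians had the lowest possible value. They still stood at percentiles 7.6, 8.8, 11.3 and 12.7 of random lists, above the limit of 2.5. None of 21 neuronal markers was detected, with elav at 0.502 ± 0.25 (SD, n = 3), Rbp9 at 0.442 ± 0.263 and nSyb at 0.0458 ± 0.0625. The neuronal medians were -3.32, -3.32 and -3.11, where -3.32 is the value of a window with no signal. None of 9 fat body and yolk genes was detected, with medians of -3.32, -2.54 and -2.87. Among these apolpp had 0.291 ± 0.199, Yp3 0.158 ± 0.235 and Yp1 0.103 ± 0.108. None of 11 epithelial genes was detected, with medians of -3.32 in all 3 libraries, and shg, crb and serp had 0.494 ± 0.127, 0.418 ± 0.192 and 0.0239 ± 0.0414. Of 17 muscle genes 2 were detected, Tm1 at 8.78 ± 4.48 and Zasp52 at 1.07 ± 0.559, followed by Mlp60A at 0.0136 ± 0.0236, and the medians were -3.32 in all 3 libraries. Germ line markers had medians of -0.55, -1.92 and -2.12, and 3 of 9 were detected: bgcn at 7.40 ± 1.12, which is also in the list of described targets, tud at 6.25 ± 0.642 and aub at 2.10 ± 0.130.

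Markers of hemocytes, the blood cells of the fly and the lineage to which S2-derived lines are usually likened, had medians of -1.58, -1.85 and -2.87 in replicates 1, 2 and 3. Of 24 markers 10 were detected, led by the basement membrane gene LanA at 35.2 ± 11.7 (SD, n = 3), the ferritin gene Fer1HCH at 24.7 ± 11.8 and SPARC at 15.4 ± 8.46. Chemosensory receptors had medians of -3.32 in every library, and 2 of 36 were detected, Ir40a at 2.35 ± 1.28 and Gr61a at 0.916 ± 0.426. Ir76a had 2.11 ± 2.08, with 4.32, 1.82 and 0.195. Odorant binding and seminal fluid proteins were the only list of 19 called low in every library, with medians of -3.32. Of its 77 members 1 was detected, Obp18a at 1.05 ± 0.368, followed by Obp84a at 0.240 ± 0.0865 and Obp99a at 0.138 ± 0.0849. With windows of 500 bp the chemosensory receptors were low too, and with 100 bp 0 lists were low. The call does not set the list of 77 below the others. With windows of 250 bp, the muscle, epithelial and chemosensory medians were also -3.32, the lowest possible value, in all 3 libraries. Those lists have 17, 11 and 36 members, and the call followed list size.

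**Figure D3:**
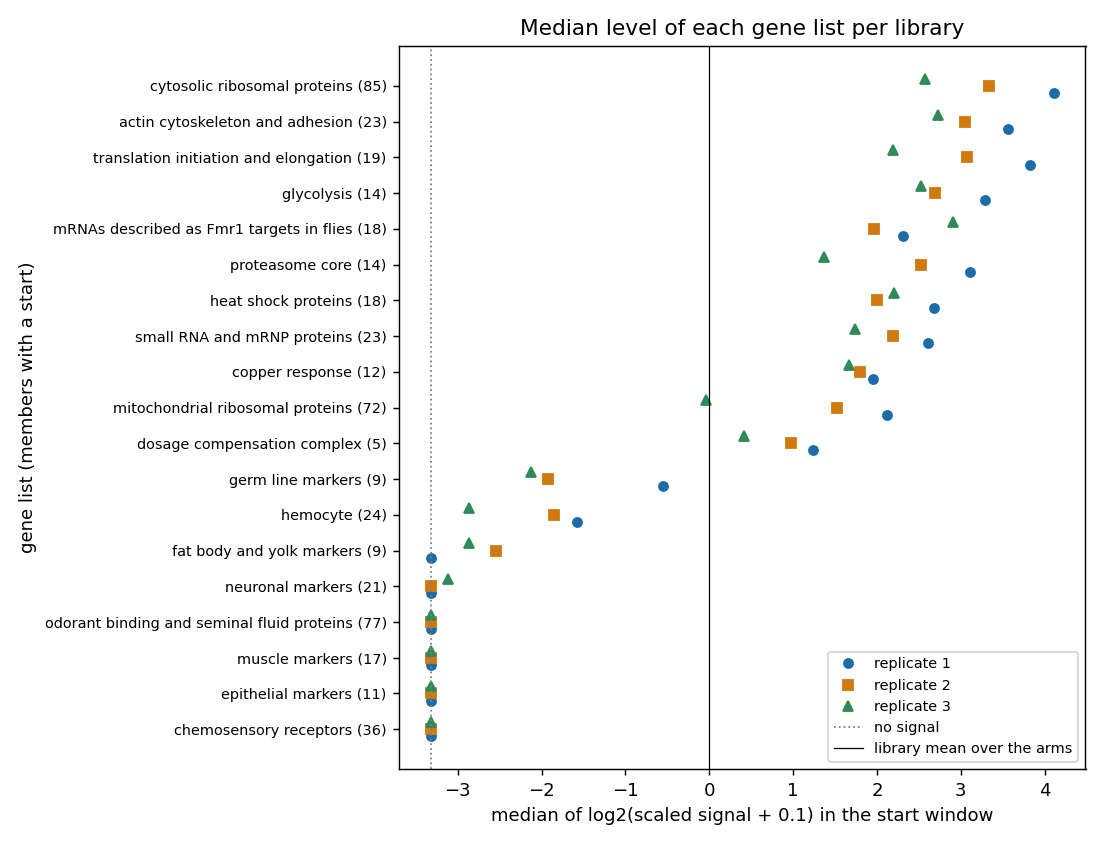
Median log2 scaled signal in the start window (horizontal axis) of 19 gene lists (vertical axis, number of members in brackets), with a point for each of the 3 replicates. The dotted line at -3.32 marks windows with no signal and the solid line the library mean, and 10 of the lists were high in every library.

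Small structured RNAs were scarce in the annotated interval of 2L. None of 13 tRNA genes was detected, with tRNA:Gln-CTG-2-4 at 0.309 ± 0.534 (SD, n = 3), tRNA:Tyr-GTA-1-3 at 0.0942 ± 0.122 and tRNA:Ser-AGA-2-4 at 0.0554 ± 0.0959. Of 4 listed spliceosomal and nucleolar RNAs, snRNA:LU was detected at 4.64 ± 6.61, and snRNA:U5:23D had 1.74 ± 3.02, with signal in replicate 1 alone, and snoRNA:kis-a 0.0515 ± 0.0891. The median log2 level of these 4 genes was -0.92, and that of the tRNA genes -3.32. The size range above 200 in the labels bears on such short RNAs. Without replicate 1, the median of the spliceosomal and nucleolar RNAs was -2.91.

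mRNAs made up nearly all detected genes of this interval. Of 535 mRNA genes 221 were detected, against 1 of 51 ncRNA genes, and the 4 pseudogenes were not detected. The highest levels belonged to RpLP1 at 419952 to 420864 with 64.2 ± 31.5 (SD, n = 3) and RpL40 at 4227699 to 4228552 with 62.9 ± 18.4, both ribosomal proteins. Next came Npc2a, a sterol-binding protein, at 40.0 ± 11, Stip1, a cochaperone of Hsp70 and Hsp90, at 35.7 ± 17.4, Taf10b at 33.6 ± 27.4 and FASN1, a fatty acid synthase, at 33.6 ± 7.33. The ETS repressor gene aop had 28.4 ± 6.98, Tango14 25.2 ± 4.66, CG4822 24.5 ± 14.5 (35.8, 29.6 and 8.16 in replicates 1, 2 and 3) and RpS21 24.3 ± 7.88. Differences among these 10 genes were not tested.

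Beyond this interval, the highest runs of tiles on the arms were taken by coordinates. After the run at Fmr1 came 2R 7781001 to 7783000 downstream of eEF1alpha1 at 379 ± 52.3 (SD, n = 3) and 2L 21678001 to 21682000 downstream of eEF2 at 373 ± 13.7. The run 2R 10245001 to 10248000, which holds a start of Arc1, had 338 ± 247 (545, 404 and 64.2 in replicates 1, 2 and 3). Runs next to RpL28 (3L 3221001 to 3222000) and at CG34330 (X 18962001 to 18963000) had 294 ± 87.4 and 275 ± 105. Act5C (X 5796001 to 5799000) had 275 ± 14.1, Hsc70-4 (3R 11070001 to 11072000) 221 ± 29.1 and His3.3B, a histone variant (X 9046001 to 9049000), 208 ± 61.3. At X 5725001 to 5727000, where no RefSeq start ran in, the level was 290 ± 281 (576, 280 and 13.3). The highest 1% of 120355 tiles held 39.3 ± 2.06% of the signal on the arms.

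Signal lay in exons. In the 2L interval, exonic bases had a scaled signal of 2.91, 3.09 and 3.08 in replicates 1, 2 and 3, intronic bases 0.0556, 0.0413 and 0.0508, and intergenic bases 0.0136, 0.00986 and 0.00907. The log2 ratio of exon over intron was 5.95 ± 0.26 (SD, n = 3) and above 0 in each of the 3 libraries (exact two-sided sign-flip permutation test, p = 0.25, the smallest this test allows with 3 libraries). Introns held 2.64%, 1.87% and 2.29% of the signal in genes. Taken per gene, the median log2 ratio over 171 genes was 4.29. Across 10896 transcript starts, the 250 bp downstream exceeded the 250 bp upstream by a log2 ratio of 2.79 ± 0.11 (exact p = 0.25, n = 3), again in each library.

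Within mRNAs, 3′ UTRs carried less signal than coding sequence at many genes. Of 166 genes, 63 had a lower 3′ UTR and 1, frtz, a higher 3′ UTR by limma, and 102 did not pass. The chaperone gene shv (2L 453108 to 454654) had no 3′ UTR signal in any library against a CDS level of 14.7, at least 75.5-fold lower by a floor of 3 reads per library (limma adjusted p = 9.8e-30). At gkt, a tyrosyl-DNA phosphodiesterase gene, the 3′ UTR was likewise at 0, at least 14.9-fold lower. CG13689, Bacc and RpS21 had log2 ratios of -4.52, -4.10 and -3.81, with a pooled standard error of 0.55, which was the same for every gene. This error is not the spread of a single gene, since Bacc had -2.59, -3.12 and -6.59 in replicates 1, 2 and 3. The genes past the threshold that lay nearest to 0 were CG3625, Pus10 and RFeSP at -1.30 and Mad at -1.31. At frtz (1711302 to 1715851, minus strand), a planar polarity gene, the ratio was 6.21, with a 3′ UTR level of 121 against 1.44 in the CDS (limma adjusted p = 2.1e-23). The gene mRpL48 on the other strand ends at 1711465 within that 3′ UTR, and the files hold no strand. Bases shared by the 2 genes were left out of both, and mRpL48 itself had a level of 2.85 ± 0.852 (SD, n = 3).

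The size of the 3′ UTR difference depended on the library. Median log2 ratios were -0.42, -0.70 and -1.92 in replicates 1, 2 and 3, and 108 of the 166 genes were below 0 in every library. Without replicate 2, 22 genes were lower, all among the 63. Without replicate 3, 81 were lower, of which 61 were among the 63, and 4 were higher: frtz, and capt, CG17260 and for, which are named because of this count. With no minimum signal, 9 of 297 genes were lower.

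Annotated 5′ UTRs, joined over all transcripts of a gene, carried less signal than coding sequence at most genes. Neither parts that these cells leave unused nor loss of coverage at the 5′ end was tested as a cause. By limma, 95 of 157 genes were lower and 0 higher, and 0 were higher at an unadjusted p under 0.05 and 0 by limma with a trend. Eno, the glycolytic enzyme enolase (2L 1724768 to 1729636), had the lowest log2 ratio at -5.99 (limma adjusted p = 2.3e-36). The standard error of 0.40 was pooled, the same for every gene, and is not the spread of a single gene. The complex I subunits ND-B14.5B and ND-B17.2 had -4.31 and -4.16, and CG3662 and CG9663 had -3.59 and -3.31. Nearest to 0 among the called genes were Cep97 at -0.88, CG11562 at -0.90, Axud1 at -0.92, and Atet and CG4896, both at -0.93. Medians were -0.66, -1.17 and -1.38 in replicates 1, 2 and 3, and 116 genes were below 0 in every library. Without replicate 2, 53 genes were lower, all among the 95. Set against the first 300 bp of the CDS alone, 3 of 156 genes were higher, capt, AIF and Traf4, which are named because of this count. Of these, capt and Traf4 were among the 95 lower genes, so their direction turned, from -1.64 to 3.71 and from -1.22 to 1.09.

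Along the whole mRNA, divided at the middle of its exons, most genes showed no difference past the threshold. By limma, 14 of 237 genes were higher in the 3′ part, 8 were lower and 215 did not pass. Of the genes already named, frtz, Eno, CG3662, capt, CG4822 and Traf4 were higher, with log2 ratios of 3.71, 2.52, 2.43, 2.05, 1.44 and 1.02. RpS21, Bacc, CG13689 and gkt were lower, with -4.65, -4.41, -4.36 and -2.62. Standard errors ran from 0.15 to 0.63. Medians were 0.02, 0.04 and -0.22 in replicates 1, 2 and 3. Without replicate 3, 44 genes were higher and 32 lower, including all 14 and 8. Without replicate 1, 3 were higher (ND-15, CG3662 and frtz) and 5 lower (CG13689, Slh, Bacc, RpS21 and gkt), and without replicate 2, 8 were higher and 13 lower, of which 7 were among the 8.

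**Figure D4:**
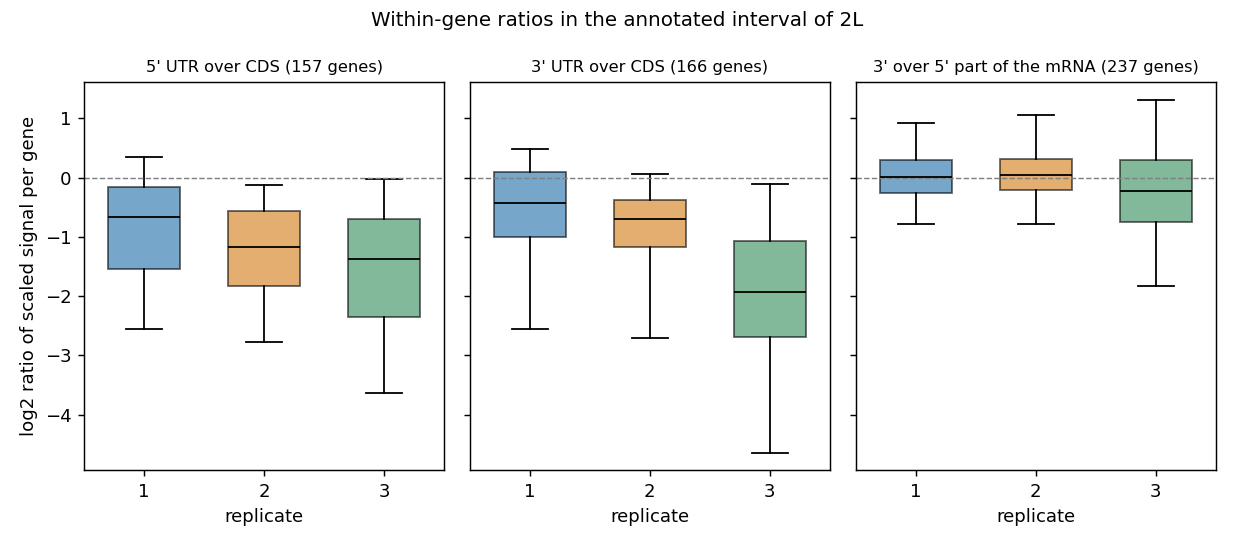
Log2 ratio of scaled signal per gene (vertical axis) for 5′ UTR over CDS, 3′ UTR over CDS, and the 3′ over the 5′ part of the mRNA, with a box for each replicate (horizontal axis) showing median and quartiles, and whiskers at percentiles 5 and 95. Medians of 3′ UTR over CDS were -0.42, -0.70 and -1.92, and those of the 3′ over the 5′ part 0.02, 0.04 and -0.22.

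By chromosome, the X carried 13.3 ± 4.02% of the signal (SD, n = 3; 10.2%, 11.8% and 17.8% in replicates 1, 2 and 3). The arms 2L, 2R, 3L and 3R carried 11.5 ± 1.53%, 15.6 ± 1.95%, 13.6 ± 2.86% and 18.1 ± 4.03%, and chromosome 4 carried 0.576 ± 0.111%. Per base, the X stood at a log2 ratio of -0.06 ± 0.17 to the autosomal arms, with -0.17, -0.15 and 0.13 in replicates 1, 2 and 3 (exact two-sided sign-flip permutation test, p = 0.5). Chromosome 4 stood at -0.51 ± 0.50, with -0.24, -0.20 and -1.08 (exact p = 0.25). This sign-flip test gives no p under 0.25 with 3 libraries. Without the highest 1% of tiles the ratio of chromosome 4 was -0.13, with 0.15 and 0.19 in replicates 1 and 2 and -0.72 in replicate 3, and over the median of detected tiles it was -1.04. Without replicate 3 it was -0.22.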

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

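The comparisons of the report use the arms of dm3, and 8 other sequences carried signal above what a count of 0 allows, at most 4.4e-05% of a library (3 reads). The unplaced sequence U held 19.0 ± 8.35% of the signal (SD, n = 3), with 25.9%, 21.5% and 9.72% in replicates 1, 2 and 3. XHet held 5.79 ± 4.60% (10.02%, 6.44% and 0.899%) and the mitochondrial genome M 2.05 ± 1.43% (2.94%, 2.81% and 0.394%). The heterochromatic sequences 3LHet, 2RHet, 3RHet, 2LHet and YHet held 0.212 ± 0.0178%, 0.155 ± 0.0235%, 0.131 ± 0.00562%, 0.0402 ± 0.00124% and 0.000413 ± 0.000103%. Per base, YHet had a scaled signal of 0.00173, 0.00239 and 0.00195 in replicates 1, 2 and 3, below the 0.0136, 0.00986 and 0.00907 of intergenic bases in the 2L interval. The other 7 sequences lay above that intergenic level in every library.

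A few tiles held most of the signal on U and XHet. The tile at U 5727001 to 5728000 held 8.32% of a library on average (10.9%, 8.49% and 5.53% in replicates 1, 2 and 3), XHet 191001 to 192000 held 4.46% (8.08%, 4.80% and 0.504%), and U 9063001 to 9064000 held 3.19% (4.96%, 4.23% and 0.380%). On M the leading tiles, 2001 to 3000 and 12001 to 13000, held 0.506% and 0.448%. Which RNAs these tiles hold was not examined, since no sequence of this build was used here. On U, XHet and M the share was lowest in replicate 3, the library with the largest share on the arms (88.4%).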

How the results depend on the processing

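The heat shock list fell from a mean of medians of 2.29 to -0.71 with windows of 100 bp and was no longer high, and cytosolic ribosomal proteins rose from 3.34 to 4.99 with 500 bp. Without the highest 1% of tiles, chromosome 4 was above the autosomal arms in replicates 1 and 2 (0.15 and 0.19). A rule asked that a value move by less than the replicate spread, or by at most 1.5 times for counts. For ratios with a sign-flip test it asked only that the sign hold, since no p could fall under 0.05. Among the main results of each comparison, 59 of 68 values under other settings met the rule. With 1 replicate left out, 39 of 48 did. Values that met it by sign alone include exon over intron, which went from 5.95 ± 0.26 to 4.29 by the median over genes. Chromosome 4 likewise went from -0.51 ± 0.50 to -1.04 over the median of detected tiles. For single lists and genes, 61 of 84 values under other settings met the rule. With 1 replicate left out 75 of 75 did, but this was fixed in advance. The mean of 2 libraries always lies within the SD of all 3 around their mean. The same limit applies to each main result that is a mean over libraries judged by the replicate spread. Over all tiles with signal, r was 0.933 between replicates 1 and 3 and 0.955 between 2 and 3. The highest tiles held 29.9% of the signal with 5-kb tiles and 15.7% when the highest 0.1% were taken. Lists low in every library numbered 2 with windows of 500 bp and 0 with 100 bp, where the Fmr1 window had 0.0828. With no minimum signal, 9 genes had a lower 3′ UTR, with 297 genes tested, and against the first 300 bp of CDS 3 had a higher 5′ UTR, of which capt (3.71) and Traf4 (1.09) were lower in the main comparison. Leaving out each replicate gave 22 to 81 genes with a lower and 1 to 4 with a higher 3′ UTR, 53 to 93 with a lower 5′ UTR, and 3 to 44 higher and 5 to 32 lower in the 3′ part of the mRNA, where lower genes outnumbered higher ones without replicate 1 (5 and 3) or 2 (13 and 8). No called gene of the main comparison changed sign with 1 replicate left out. The cause was not tested for any of these changes. The fits that leave out 1 replicate use 2 libraries, and the depth of replicate 1 (34.2 reads per tile at a level of 1) limits the weak features. Detection of 222 genes ranged from 151 to 268 under other settings. No paired analysis was possible because the labels give 1 group.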

Other observations

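The tests on replicate 3 alone and the division of the Fmr1 locus into blocks were chosen only after the result was seen. The trend with exonic length and the ratio of the Fmr1 body to its start window were not planned comparisons either. The design gives 1 group, so no biological explanation was tested for any pattern.

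Genes with long mRNAs stood out in replicate 3. Genes of 3261 to 22888 bp were higher there than in replicate 1 by a median log2 difference of 0.39, and those of 497 to 1246 bp lower, at -1.34. The same order of lengths held between the other libraries, with a Spearman rho across 237 genes of 0.80 for replicate 2 minus 1 and 0.46 for replicate 3 minus 2. Genes are not independent replicates. The mean level of a gene did not order these differences, with a rho of -0.06 for replicate 2 minus 1 and -0.02 for replicate 3 minus 1.

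The first pattern is this trend of replicate 3 minus replicate 1 with exonic length (rho 0.65, bootstrap SD 0.044). Thinning replicate 3 to the depth of replicate 1 gave a rho of 0.651 and moved the level of a gene by a median of only 0.04 on the log2 scale. The medians of the length classes ran from -1.34 to 0.39. In these 237 genes this argues against the number of reads counted as the source of the trend. Thinning leaves any other difference that goes with depth untouched, so such differences stay open. Loss of coverage within 300 bp of the ends of transcripts, which weighs most on short mRNAs, is argued against in 197 genes only. These kept at least 300 bp of exon interior, and its rho was 0.577, against 0.590 for all exonic bases of the same genes. The former was 0.977 times the latter (95% bootstrap interval 0.922 to 1.04). The shortest genes kept too little interior to be tested, so for them such loss stays open. Differences in fragment size selection, in RNA recovered by the antibody or in library preparation may underlie the trend and stay open, since the labels give the same values for the 3 libraries.

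The next pattern is the low signal of 3′ UTRs. Over the 3 libraries, the median log2 ratio was -0.564 without the last 300 exonic bp, against -0.75 for the whole 3′ UTR of the same 87 genes, and -0.600 for the first 100 bp of 3′ UTR over the last 300 bp of CDS in 165 genes. In both tests the libraries spread widely (0.04, -0.39 and -1.34 in the former, -0.20, -0.34 and -1.27 in the latter), so loss of coverage at the 3′ end and annotated 3′ UTR that these cells leave unused cannot be told apart from other causes over the 3 libraries. In replicate 3 alone the ratios were -1.34 (95% bootstrap interval over genes -1.71 to -1.003) and -1.27 (-1.50 to -1.06), which argues against either as the whole cause in that library. A loss of reads from UTRs during fragmentation, alignment or immunoprecipitation could be involved and stays open.

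The last pattern is the height of the Fmr1 locus away from its starts. The highest tile within 10 kb downstream was 73.1 times the start window, against a median of 1.87 over genes. Only 0.312% of 6085 other genes had as large a ratio, which argues against the unevenness seen at other genes. A candidate explanation is that reads from the tagged copies, which may lack the 5′ and 3′ ends of the natural mRNA, fall on the high blocks at 705 and 791 and not on the flanks at 6.99 and 25.4. This was not tested, since the sequence of the transgenes and exon models of 3R were not used here, and strong recovery of Fmr1 mRNA by its own protein stays open as well.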
